A study of Mus musculus with 12 samples.

How the data were processed

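RNA was sequenced from the hearts of 12 C57BL/6N mice at 9 months of age, 6 wild type (WT) and 6 with the Lemd2 knock-in (KI), with 1 library per animal. Libraries were made with a stranded kit that selects messenger RNA, per the submitters' protocol. Reads were trimmed with cutadapt 2.5 and aligned with STAR 2.7.2b, per the submitters' processing notes. The deposited values are expected counts per gene, not normalized, which the authors made with featureCounts 1.6.4. Per the file headers, reads on the reverse strand were counted over the whole gene span, introns included, against a RefSeq annotation of mouse genome build GRCm38.p6. Reads with several alignments, and reads that overlap several genes, were split as fractions between the genes, per the file headers. Of the nonzero values of a library, 42.4% to 47.5% are therefore not whole numbers. Related genes and overlapping genes can share reads under this scheme.

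The table holds 39331 gene entries, and the total count per library ranged from 27.9 to 44.6 M (units of 1000000). Of the 105 genes singled out by the rule given later, 17 overlap another annotated gene on the same strand, and for 4 of them the neighbour's count was above 10% of their own. These 4 are TrnI, which overlaps ND1, ATP6 and COX3, which overlap each other, and Slc7a5, which overlaps Gm42049.

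The groups were taken from the sample labels, which name 1 comparison, KI against WT. Genes were kept with filterByExpr of edgeR 4.0.16 (a minimum count of 10 and a minimum total of 15), which left 15602. Library sizes were scaled by TMM, and the groups were compared with the edgeR quasi-likelihood test in R 4.3.3, without covariates, on the counts as deposited. The p values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. Errors of log2 fold changes are standard errors (SE), fold changes are KI over WT, and abundances are CPM (counts per 1000000 counts), scaled by the TMM factors and given as mean and SD. A prior count of 2 was used for log2 CPM. Measures with 1 value per library were compared with two-sided exact permutation tests, and where 4 such library measures or 6 such tests formed a family, adjusted p values are over that family.

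Before the data were examined, the test, the alternatives, 38 gene lists and the rule for singling out genes were fixed. That rule takes Lemd2, the 12 largest rises and 12 largest falls among genes past the threshold with an average log2 CPM of at least 1 and every KI library on 1 side of the WT mean of log2 CPM, up to 4 members of each list with the smallest adjusted p, and the 3 genes with the smallest adjusted p in each direction. Predicted or unnamed gene models were not eligible for the largest rises and falls. Where fewer than 2 members of a list passed, its most abundant members made up the number. Some genes that the rule takes are not reported here. Genes outside the rule are marked as chosen after their values were seen.

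Lists with 5 or more members among the genes tested were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 31 lists so tested. Beside it stand camera with a correlation estimated from the data and fry, which asks whether the members of a list move 1 way on balance without comparing them with other genes. For each list the members past the threshold were counted both over all genes tested and adjusted over the list alone. The sex-linked list served as a check. Xist had at most 6.5 counts in a library while the Y-linked markers summed to at least 4790, so all 12 libraries come from males and the planned covariate for sex was not run.

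Alternatives fixed in advance were size factors of the RLE kind, scaling by library total alone, no filter, a filter of CPM above 1 in 6 libraries, the DESeq2 1.42.0 Wald test (counts rounded to 0 decimals), voom with quality weights, a test against a fold of 1.2, a block on the replicate number, 1 surrogate variable (sva 3.50.0), each library left out in turn, and the KI libraries 3, 4 and 5 left out or kept alone. These 3 libraries carry consecutive numbers and share an age tag in their titles, which the other KI titles lack. Leaving out the genes of the mitochondrial chromosome was added after the data were seen. The groups were also compared in 100 groupings of the 12 libraries into 6 and 6, the real one included.

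The fit was tested on simulated data with 6 libraries per group and 15452 genes, of which 220 were changed. It called 20.0% of the genes changed 1.25-fold, 54.0% of those changed 1.5-fold, 80.0% at 2-fold and 98.0% at 4-fold, with 50 genes at each size, and 6.38% of the genes called were unchanged. The camera test gave an adjusted p of 3.08e-16 for a list of 20 genes raised 1.3-fold and 0.633 for an unchanged list. Figures were drawn with matplotlib 3.10.9.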

Results

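Gene expression was measured by RNA sequencing in hearts of 12 male C57BL/6N mice aged 9 months. The WT group and the KI group held 6 animals each, and each animal gave 1 library, so n = 6 per group throughout. The KI mice carry a leucine-to-arginine substitution at amino acid 13 of LEMD2, a protein of the inner nuclear membrane. The total count, in units of 1000000 (M), was 40.8 ± 2.73 M (SD, range 38.3 to 44.6) in WT and 36.6 ± 6.10 M (SD, range 27.9 to 42.9) in KI, a difference with a two-sided exact permutation p of 0.147. The lowest totals were those of KI 3 (27.9 M), KI 5 (31.8 M) and KI 4 (34.9 M), which carry consecutive numbers, by either number of their titles. Each title holds 2 numbers, and the titles do not say what each of them counts. By the second, each run of neighbouring numbers held 1 group only, so that series and the genotype cannot be told apart. By the first, WT 2 shares a number with KI 4. Tags that the sources used here do not explain stand in some KI titles, old for KI 2, new for KI 6 and an age tag for KI 3 to 5. The first number of KI 1 and of KI 2 joins 2 numbers, and the titles do not say whether more than 1 sample went into these libraries. Genes of the mitochondrial chromosome took 37.0% ± 2.28 (SD) of the counts in WT and 32.1% ± 1.17 (SD) in KI (two-sided exact permutation p = 0.00216, adjusted over 4 library measures 0.00577). The first principal component of log2 CPM held 25.9% of the variance and the second 18.2%.

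The comparison of KI with WT asks what the Lemd2 substitution changes in heart gene expression at this age. Lemd2 itself (Gene ID 224640, GRCm38.p6 chromosome 17, 27189600 to 27205470, minus strand) fell from 27.4 ± 1.97 CPM in WT to 21.3 ± 2.88 CPM in KI (SD, n = 6 each). Its log2 fold change was -0.36 (SE 0.09, adjusted p = 0.0213), and 6 of 6 KI libraries lay below the WT mean. The fold remained negative but missed the threshold when libraries were scaled by their totals (-0.21, adjusted p = 0.161), when only KI 3 to 5 were compared with WT (-0.23, adjusted p = 0.0631) and with a block on the replicate number (-0.37, adjusted p = 0.0889). Over all the alternatives its adjusted p ranged from 0.00104 (DESeq2) to 0.558 (a test against a fold of 1.2). A gene count cannot show the point substitution, so it does not check the genotype.

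Of the 15602 genes tested, 688 were higher and 677 lower in KI, 1365 in all, and 4023 had an unadjusted p under 0.05. The median absolute log2 fold change of the genes called was 0.41, and 175 of the higher genes against 21 of the lower ones differed by 2-fold or more. Protein-coding genes made up 657 of the higher and 630 of the lower genes, and long noncoding RNAs 28 and 41. In 613 of the genes called, and 681 of all genes tested, the KI and WT values did not overlap, where chance gives 0.216%, or 33.8 genes. Genes higher in KI were 50.4% of those called, but scaling by library total moved the median of all genes by 0.15 on the log2 scale and made them 93.9%, so directions here are relative to the TMM scaling. The counts also moved when a library was left out, from 390 (without WT 6) to 714 (without WT 4) higher and from 338 (without KI 3) to 833 (without KI 1) lower. Those of the higher genes were 402 without WT 2, 399 without KI 3 and 423 without KI 4. Those of the lower genes were 355 without WT 2, 435 without WT 3, 406 without WT 5, 378 without WT 6, 352 without KI 4 and 386 without KI 5.

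**Figure D1:**
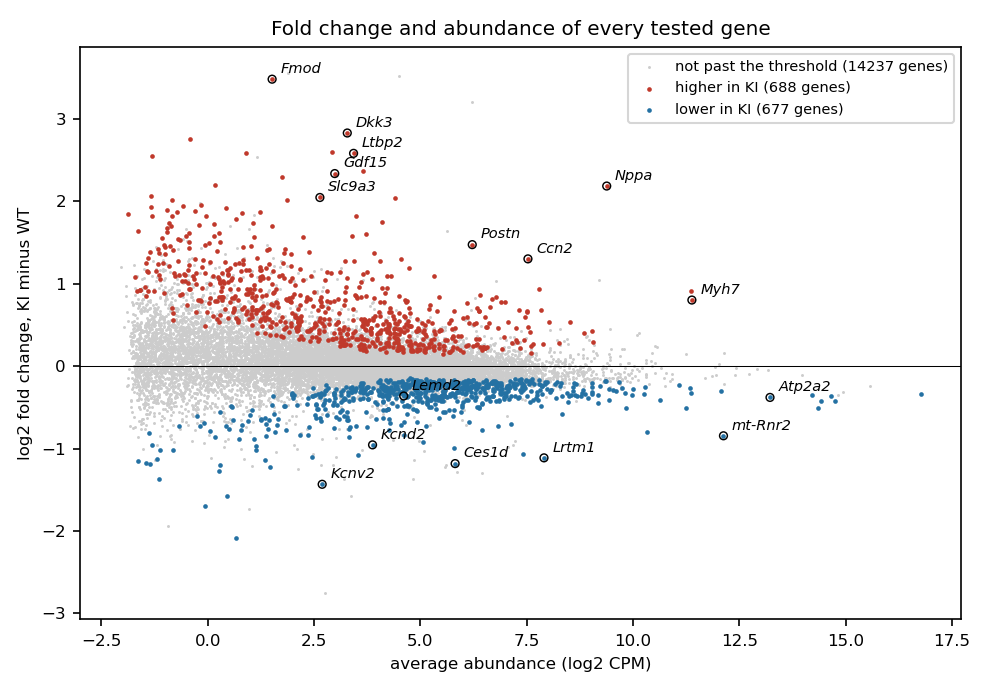
Log2 fold change of KI over WT (vertical axis) against average log2 CPM (horizontal axis) for the 15602 genes tested, with genes past an adjusted p of 0.05 coloured by direction. The 688 higher genes reach larger changes than the 677 lower ones, with 175 and 21 at 2-fold or more.

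The smallest adjusted p of any gene belonged to Kcnv2 (Gene ID 240595, chromosome 19), which encodes a modulatory potassium channel subunit and fell from 9.34 ± 1.75 to 3.45 ± 0.46 CPM (SD; log2 fold change -1.43, SE 0.13, adjusted p = 0.000443, n = 6 each). Agtpbp1 (-0.49, SE 0.05) and the unnamed gene Gm36703 (-1.11, SE 0.13) had the next smallest among lower genes. Among higher genes, Plcg2 (0.55, SE 0.06) and the sodium-proton exchanger gene Slc9a3 (2.04, SE 0.22) each had an adjusted p of 0.000693. Gdf15 (Gene ID 23886, chromosome 8), a secreted stress-responsive cytokine, rose from 2.61 ± 0.96 to 13.2 ± 4.35 CPM (SD; log2 fold change 2.33, SE 0.26, adjusted p = 0.000693), in 6 of 6 KI libraries.

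The 12 largest rises included Fmod (3.48, SE 0.83), Dkk3 (2.83, SE 0.67), Comp (2.60, SE 0.55), Ltbp2 (2.58, SE 0.42), Thbs4 (2.36, SE 0.50), Col12a1 (2.30, SE 0.48), Cilp (2.03, SE 0.42) and Sfrp2 (2.02, SE 0.30). KI 6 held much of several of these rises. Without it Fmod was at 1.87 (adjusted p = 0.0104), Comp at 1.89 (0.0173), Thbs4 at 1.63 (0.0111) and Col12a1 at 1.69 (0.0154). Dkk3, at 64.4 CPM in KI 6 against 12.9 in the next library, went from 7.09-fold to 3.04-fold without it (adjusted p = 0.0151). Dkk3 missed the threshold without WT 6 (adjusted p = 0.0514). Sizeable falls were seen in Ces1d, a carboxylesterase gene (-1.18, SE 0.20, adjusted p = 0.00489), Lrtm1 (-1.11, SE 0.25), the mitochondrial transfer RNA gene TrnI (-1.06, SE 0.24), which overlaps ND1, Cngb3 (-1.01, SE 0.22), mt-Rnr2 (-0.85, SE 0.11) and Pla2g5 (-0.84, SE 0.13). Less firm were Aqp4 (-1.22, SE 0.34), Ccl11 (-0.97, SE 0.25) and Ano5 (-0.86, SE 0.21), which passed the threshold in 3, 6 and 10 of the 12 fits that left out 1 library. Their highest adjusted p were 0.0865 for Aqp4 (without WT 3), 0.0684 for Ccl11 (without KI 3) and 0.0527 for Ano5 (without KI 3).

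**Figure D2:**
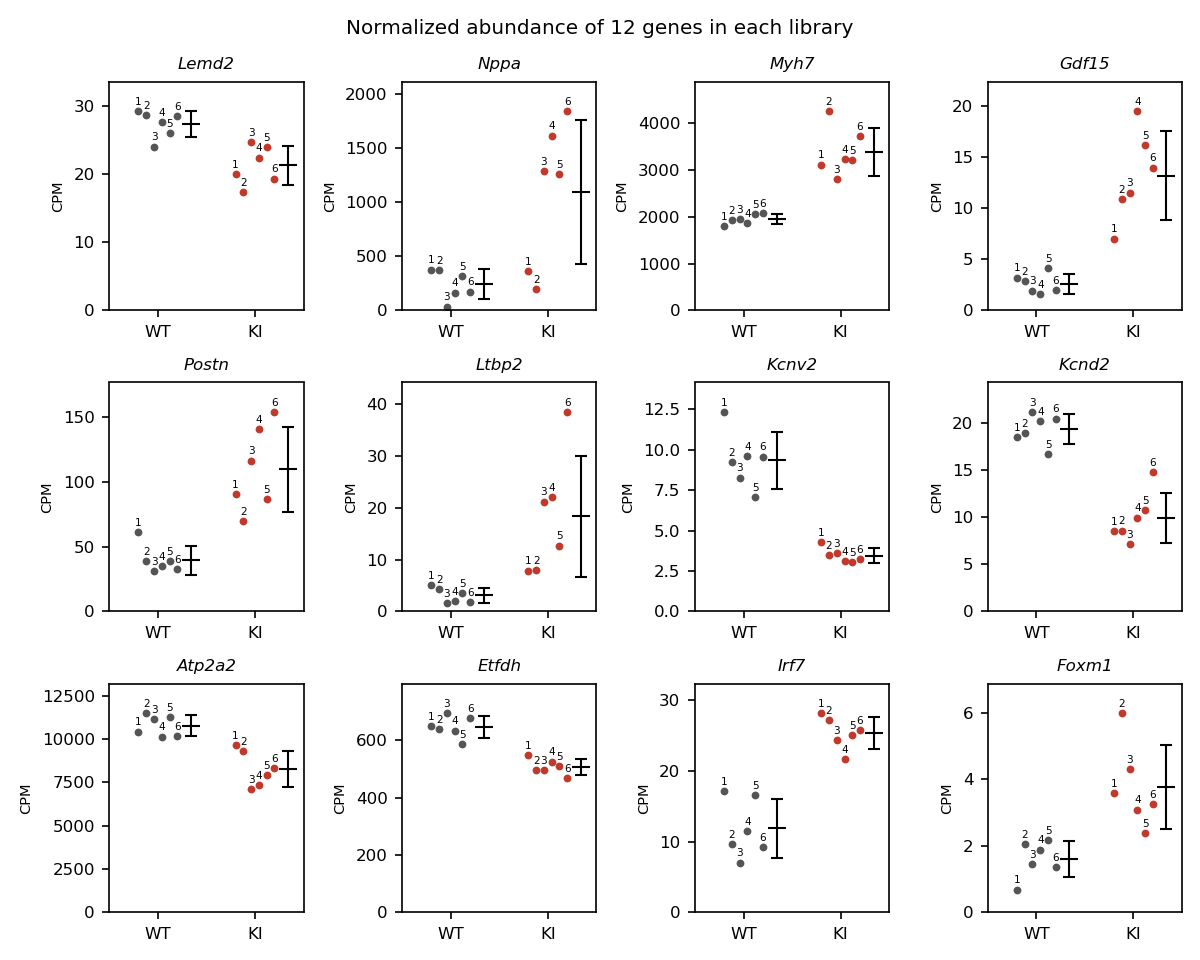
CPM of 12 genes in each library (vertical axes), WT and KI side by side, with the replicate number beside each point and bars showing mean and SD. Lemd2 lay at 27.4 CPM in WT and 21.3 in KI, and Gdf15 at 2.61 and 13.2.

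In the extracellular matrix list 23 of the 32 members tested were higher in KI and 0 lower (27 and 0 adjusted over the list alone). The counts of lower members are by edgeR, and 27 members had an unadjusted p under 0.05 in all, with 23 calls by DESeq2 and 22 by voom. Postn, which encodes periostin, rose from 39.4 ± 11.1 to 109 ± 33.0 CPM (SD; log2 fold change 1.47, SE 0.21, adjusted p = 0.00247), Col8a1 by 1.09 (SE 0.12), Ltbp2 by 2.58 (SE 0.42) and Sparc by 0.53 (SE 0.09), each in 6 of 6 KI libraries. The median log2 fold change of the list was 0.80 (camera adjusted p = 1.28e-27). Its adjusted p = 0.121 with an estimated correlation, and 1 of 100 groupings of the libraries, the real one, gave a camera p as small. With KI 1, 2 and 6 alone the median was 0.98 (9 members called), and with KI 3 to 5 alone 0.50 (20 members called). Fibroblast markers had a median of 0.40, with 3 of 12 higher (7 adjusted over the list alone), namely Mfap5 (1.09, SE 0.18), Pi16 (0.84, SE 0.17) and Col1a1 (0.86, SE 0.19), the last also on the matrix list. That list had a camera adjusted p of 1.75e-06, an adjusted p = 0.234 with an estimated correlation, and a camera p matched in 13 of 100 groupings. Without KI 2, 7 of its members were called.

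Genes of cardiac stress and the fetal program were higher in 6 of 19 (10 adjusted over the list alone), with a median of 0.45. Myh7, the slow myosin heavy chain gene, rose from 1946 ± 106 to 3389 ± 514 CPM (SD; log2 fold change 0.80, SE 0.09, adjusted p = 0.000693) in 6 of 6 KI libraries. Uchl1 (1.02, SE 0.15) and Ankrd1 (0.90, SE 0.17) also rose, as did Ccn2, from 107 ± 34.2 to 262 ± 65.8 CPM (SD, adjusted p = 0.00500). Nppa (Gene ID 230899, chromosome 4), which encodes atrial natriuretic peptide, rose from 240 ± 137 to 1091 ± 668 CPM (SD; 2.18, SE 0.58, adjusted p = 0.0341). KI 3 to 6 lay between 1257 and 1836 CPM, while KI 1 (361) and KI 2 (195) lay inside the WT range of 35.2 to 377. With KI 1, 2 and 6 alone its adjusted p was 0.244. Nppa passed the threshold in only 4 of the 12 fits that left out 1 library, with the highest adjusted p without WT 6 (0.0735), and without KI 6 its log2 fold change was 1.97 (adjusted p = 0.0628). For the list the camera adjusted p was 7.98e-08, the adjusted p = 0.158 with an estimated correlation, and 6 of 100 groupings gave a camera p as small.

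Sarcomere genes had a camera adjusted p of 0.375 but were called higher under scaling by library total (0.0105, with 7 members called, all higher). With TMM their median of -0.0033, mean of 0.07 and upward test differ in sign. Of 24 members, Myh7 was higher and Tnni3, the cardiac troponin I gene, lower (-0.26, SE 0.06, adjusted p = 0.0222), with 3 higher and 1 lower adjusted over the list alone. Tnni3 was also the 1 lower member of the 10 ventricular cardiomyocyte markers (1 adjusted over the list alone), whose median was -0.04 but 0.12 under scaling by library total (camera adjusted p = 0.195, and 0.0494 without WT 4). Tnni3 kept its call in 6 of the 12 fits that left out 1 library, with the highest adjusted p of 0.0639 without WT 2. Myh6, another of these markers, was at -0.11 (SE 0.08, adjusted p = 0.424), and at 0.04 under scaling by library total. Atrial cardiomyocyte markers had 2 of 6 members higher (4 adjusted over the list alone), Dkk3 and Nppa, both also named above, and a median of 1.32 that was 0.32 without KI 6 (camera adjusted p = 0.133, but 0.0251 without KI 2, 0.0121 with KI 1, 2 and 6 alone and 0.0328 with no filter). Without KI 2, 4 atrial markers were called higher, and without WT 6 edgeR called 0. Without KI 6 it called 1 higher and 2 lower, and with only KI 3 to 5 it called 3 higher and 2 lower. Myl4, chosen after its values were seen, was at 3.52 (SE 1.10, adjusted p = 0.0628), which rests on KI 6 (223 CPM, against 5.30 or less in every other library).

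Fatty acid oxidation genes were lower in 20 of 30 members and higher in 0 (23 lower adjusted over the list alone; all 23 of the members with an unadjusted p under 0.05 in edgeR were lower, and DESeq2 called 21 and voom 22). Etfdh, which encodes the electron-transferring flavoprotein dehydrogenase, fell from 646 ± 37.2 to 506 ± 27.8 CPM (SD; log2 fold change -0.35, SE 0.05, adjusted p = 0.00313). Eci1 (-0.31, SE 0.05), Etfb (-0.32, SE 0.05) and Etfa (-0.33, SE 0.06) fell too, each in 6 of 6 KI libraries. The list median was -0.29, and -0.15 with 11 members lower under scaling by library total. Its camera adjusted p was 8.25e-19, its adjusted p = 0.121 with an estimated correlation, and 2 of 100 groupings gave a camera p as small. Members called were 13 without WT 3, WT 6 or KI 4 and 12 without KI 3 or KI 5. With KI 1, 2 and 6 alone the median was -0.25, and 0 members passed the edgeR threshold, with 22 at an unadjusted p under 0.05.

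Mitochondrially encoded genes were lower in 9 of 13 (13 adjusted over the list alone), with a median of -0.35, or -0.20 under scaling by library total. Those with the smallest adjusted p were ND1 (-0.42, SE 0.08), ND2 (-0.51, SE 0.10), ATP6 (-0.42, SE 0.09) and COX3 (-0.37, SE 0.08), the last pair overlapping each other. The camera adjusted p was 1.83e-12, the adjusted p = 0.158 with an estimated correlation, and 4 of 100 groupings gave a camera p as small. The members called were 4 without WT 2, 5 without WT 5 and 4 without WT 6. With KI 1, 2 and 6 alone the median was -0.28 and edgeR called 0 members (7 at an unadjusted p under 0.05), against 8 lower and a median of -0.47 with only KI 3 to 5. Nuclear-encoded respiratory chain genes had 5 of 45 members lower (6 adjusted over the list alone), Ndufs1 (-0.28, SE 0.06), Sdhc (-0.22, SE 0.04), Ndufs4 (-0.23, SE 0.05), Sdha (-0.26, SE 0.07) and, chosen after its values were seen, Uqcrb (-0.17, SE 0.05). Their median was -0.10 but flipped to 0.06 under scaling by library total, where 4 members were called higher and 1 lower and the camera adjusted p was 0.0608 against 1.75e-06 (0.0842 by fry). The adjusted p = 0.485 with an estimated correlation, and 21 of 100 groupings gave a camera p as small. Members called ranged from 2 (without WT 2) to 9 (without WT 4), and Sdha kept its call in 4 of the 12 such fits (highest adjusted p 0.0752, without WT 2) and Ndufs4 lost it without WT 2 (0.0516). Glycolysis genes had 0 of 20 members past the threshold in edgeR (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 3 in DESeq2 and 3 in voom), and their median of 0.0055 and mean of 0.01 stood against a downward test (camera adjusted p = 0.947), while 7 members were called higher under scaling by library total. The most abundant were Aldoa (0.04, SE 0.07) and Ldhb (-0.18, SE 0.07), the latter past the threshold without WT 1 (adjusted p = 0.0465).

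Calcium handling genes were lower in 4 of 15 (5 adjusted over the list alone): Hrc (-0.41, SE 0.07), the SERCA2 gene Atp2a2 (-0.38, SE 0.08), Trdn (-0.37, SE 0.08) and the phospholamban gene Pln (-0.30, SE 0.07). Atp2a2 fell from 10774 ± 596 to 8278 ± 1027 CPM (SD, n = 6 each, adjusted p = 0.0138). With KI 1, 2 and 6 alone edgeR called 0 members (4 at an unadjusted p under 0.05), with Atp2a2 at -0.25 (adjusted p = 0.153) and Trdn at -0.23 (0.185), while with only KI 3 to 5 it called 5 lower. There Atp2a2 was at -0.55 and Trdn at -0.54. Pln missed the threshold without WT 2 (adjusted p = 0.0553), WT 5 (0.0519), WT 6 (0.0514) or KI 4 (0.0518). The list median of -0.10 flipped to 0.05 under scaling by library total, where the list was still called lower (0.00640) with 2 members called higher and 3 lower, while Hrc, Atp2a2, Trdn and Pln stayed negative. Its camera adjusted p was 0.00353, its adjusted p = 0.225 with an estimated correlation, and 7 of 100 groupings gave a camera p as small. Ion channel and conduction genes were lower in 9 of 31 (11 adjusted over the list alone), with Kcnv2, Kcnd2, which encodes a channel of the transient outward current (-0.96, SE 0.14, adjusted p = 0.00272) and Kcnj5 (-0.41, SE 0.08) among them. The list median of -0.10 was 0.03 under scaling by library total, where the list was still called lower (6.69e-08, with 5 members called, all lower). Its camera adjusted p was 5.72e-06 and its adjusted p = 0.121 with an estimated correlation, and only the real grouping of 100 gave a camera p as small. Intercalated disc genes had 0 of 15 members past the edgeR threshold (0 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 in DESeq2 and 1 in voom), with Dsp at 0.07 (SE 0.09) and Fhl2 at -0.14 (SE 0.07, or 0.01 under scaling by library total), and a camera adjusted p of 0.230. With only KI 3 to 5 this list was called lower (0.0323, with 2 members lower), and under scaling by library total 4 members were higher.

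**Figure D3:**
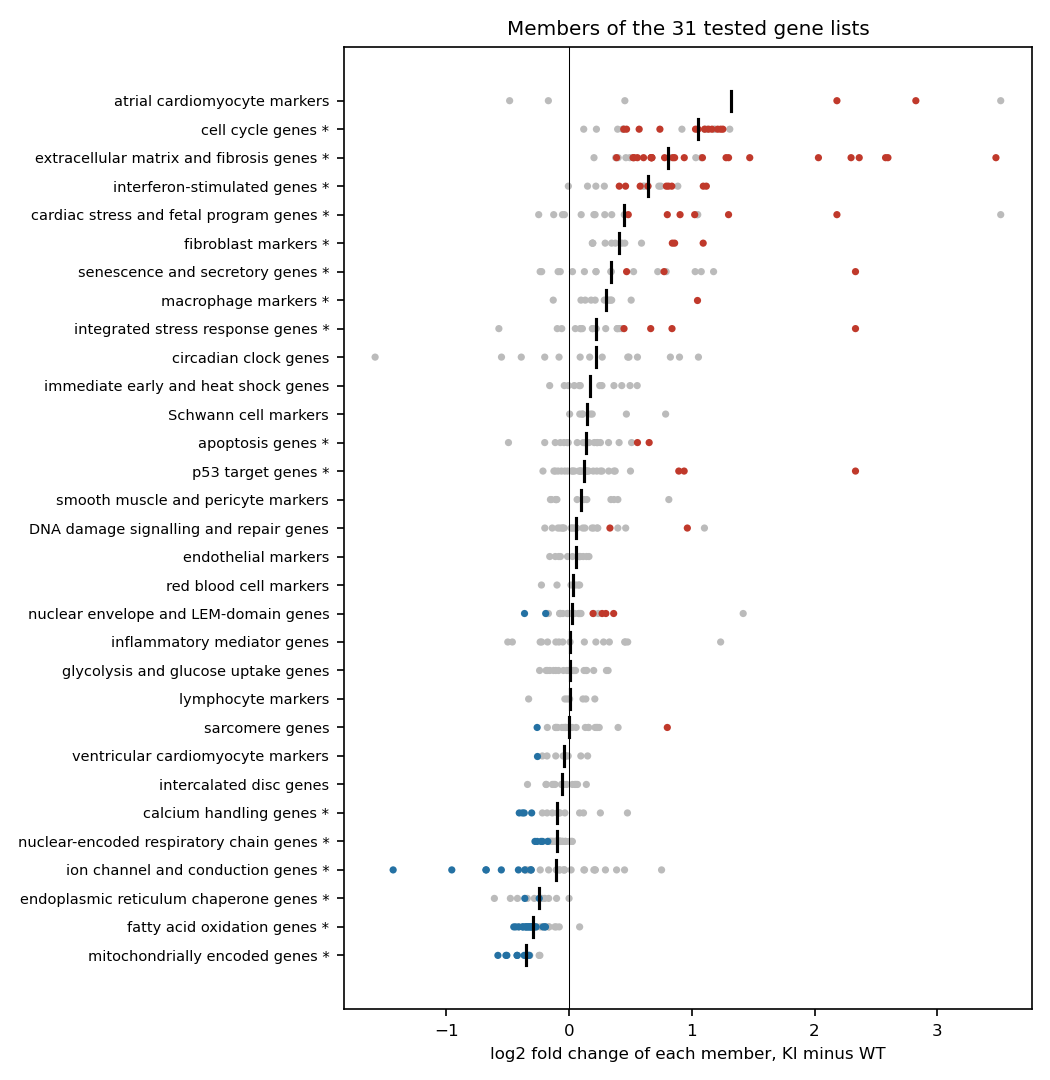
Log2 fold change (horizontal axis) of each member of the 31 lists tested, with a black bar at each median, members past the threshold in red (higher) or blue (lower), and an asterisk at lists past a camera adjusted p of 0.05. Medians were 0.80 for extracellular matrix genes and -0.29 for fatty acid oxidation genes.

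Of the 24 nuclear envelope genes, 4 were higher and 2 lower under TMM scaling (5 and 3 adjusted over the list alone), with a camera adjusted p of 0.654. Under scaling by library total all 8 members called were higher, with a median of 0.17 (camera adjusted p = 0.0767). Tmem43 (0.30, SE 0.07) and Tor1aip2 (0.20, SE 0.05) were higher. So were the lamin genes Lmna (0.27, SE 0.08, adjusted p = 0.0424) and Lmnb1 (0.36, SE 0.11, adjusted p = 0.0495), chosen after their values were seen. Another lamin gene, Lmnb2, also chosen afterwards, did not pass the threshold (0.20, SE 0.11, adjusted p = 0.265). Lemd2 and Tor1aip1 (-0.19, SE 0.05) were lower. Tor1aip1 and Tor1aip2 passed the threshold in 6 and 3 of the 12 fits that left out 1 library, with highest adjusted p of 0.0596 (without WT 5) and 0.103 (without WT 2). Leaving out 1 library gave 1 to 3 higher and 1 to 3 lower members. As Tmem43 passed in all 12 such fits, neither lamin gene was called in those with 1 higher member. These were the fits without WT 1, WT 2, WT 6, KI 2, KI 4 or KI 6.

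Targets of p53 were higher in 3 of 30 (4 adjusted over the list alone), Gdf15, Phlda3 (0.89, SE 0.16) and Psrc1 (0.94, SE 0.18), while Cdkn1a was at -0.09 (SE 0.36, adjusted p = 0.912), chosen after its values were seen. Cdkn1a spread widely in WT (35.6 ± 27.6 CPM, against 33.5 ± 4.28 in KI, SD), and only 1 KI library lay below its WT mean of log2 CPM. For the list the camera adjusted p was 0.00353 (0.0613 with only KI 3 to 5), the adjusted p = 0.121 with an estimated correlation, and 6 of 100 groupings gave a camera p as small. DNA damage genes were higher in 2 of 24 (4 higher and 1 lower adjusted over the list alone), Fancd2 (0.96, SE 0.22) and Rad50 (0.33, SE 0.10), with a camera adjusted p of 0.131. That list was called without WT 4 (0.0479), with KI 1, 2 and 6 alone (0.0135) and under scaling by library total (0.0408, with 8 members called, all higher). With only KI 3 to 5 it was not called (0.775), and edgeR called 0 members higher and 2 lower. Rad50 kept its call in 3 of the 12 fits that left out 1 library, the highest adjusted p being 0.101 without WT 5. Senescence and secretory genes were higher in 3 of 19 (4 adjusted over the list alone), Gdf15, Igfbp7 (0.77, SE 0.11) and Timp2 (0.47, SE 0.11), the last not past the threshold without WT 6 (adjusted p = 0.0531). Their camera adjusted p was 4.58e-05 and the adjusted p = 0.121 with an estimated correlation, with 5 of 100 groupings as small. Apoptosis genes were higher in 2 of 21 (8 higher and 2 lower adjusted over the list alone), Bcl2 (0.65, SE 0.15) and Casp12 (0.56, SE 0.13). Their camera adjusted p was 0.0371 and the adjusted p = 0.121 with an estimated correlation, with 3 of 100 groupings as small. The list's call was lost with only KI 3 to 5 (0.251), where 1 member was called higher and 2 lower. It was also lost with voom (0.0541) and without WT 1 (0.0593), WT 6 (0.0510), KI 1 (0.0577), KI 2 (0.0621) or KI 6 (0.0504). Higher members numbered 4 without KI 1, while 5 senescence genes were higher without WT 1, and from 1 to 4 DNA damage genes (4 without WT 4). Under scaling by library total 11 p53 targets, 7 senescence genes and 10 apoptosis genes were called, all higher.

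Integrated stress response genes were higher in 4 of 19 (5 adjusted over the list alone), Gdf15, Mthfd2 (0.84, SE 0.16), Slc7a5 (0.45, SE 0.10), which shares its locus with Gm42049, and Nupr1 (0.67, SE 0.18). Nupr1 kept its call in 3 of the 12 fits that left out 1 library (highest adjusted p 0.0859, without WT 6). Gdf15 is a member of this list and of the p53 and senescence lists. The camera adjusted p was 0.000488, the adjusted p = 0.121 with an estimated correlation, and 3 of 100 groupings gave a camera p as small. Chaperone genes of the endoplasmic reticulum were lower in 2 of 13 (4 adjusted over the list alone), Dnajb9 (-0.24, SE 0.06) and Xbp1 (-0.36, SE 0.10), with a median of -0.24. Their camera adjusted p was 0.000572, with 0.113 by fry, and the adjusted p = 0.445 with an estimated correlation, with 27 of 100 groupings as small. Dnajb9 missed the threshold without WT 5 (adjusted p = 0.0519) or KI 3 (0.0501), and Xbp1 kept its call in 3 of 12 such fits (highest 0.0959, without KI 4), so members called ran from 0 (without WT 5 or KI 3) to 4 (without WT 4). Under scaling by library total 0 members were called, with Dnajb9 at -0.09 (adjusted p = 0.193) and Xbp1 at -0.22 (0.189). There the list was still called lower (camera adjusted p = 9.74e-05).

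Interferon-stimulated genes were higher in 9 of 19 (15 adjusted over the list alone), with a median of 0.64. The transcription factor gene Irf7 rose from 11.9 ± 4.13 to 25.3 ± 2.29 CPM (SD; log2 fold change 1.09, SE 0.18, adjusted p = 0.00500), Ifi27l2a by 1.12 (SE 0.21), Ddx58 by 0.41 (SE 0.08) and Oas1a by 0.79 (SE 0.16). The camera adjusted p was 1.57e-12, the adjusted p = 0.158 with an estimated correlation, and 4 of 100 groupings gave a camera p as small. Cell cycle genes were higher in 12 of 23 (21 adjusted over the list alone), with a median of 1.05, among them Foxm1 (1.24, SE 0.26), Aurkb (1.03, SE 0.24), Mcm3 (0.57, SE 0.10) and Mcm5 (0.74, SE 0.16). Mcm3 lay at 5.31 ± 0.65 CPM in WT and 7.88 ± 0.85 in KI (SD, adjusted p = 0.00531). Their camera adjusted p was 8.38e-15 and the adjusted p = 0.196 with an estimated correlation, with 10 of 100 groupings as small. The members called were 5 without WT 2, 4 without WT 6, 7 without KI 2 and 5 without KI 3. Inflammatory mediator genes had 0 of 17 members past the edgeR threshold (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 in DESeq2 and 0 in voom), with Nfkbia at 0.48 (SE 0.20) and Vcam1 at 0.33 (SE 0.15), and a camera adjusted p of 0.572. Under scaling by library total 4 of them were called higher, as were 14 interferon-stimulated genes and all 23 cell cycle genes.

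Macrophage markers had 1 of 12 members higher (2 adjusted over the list alone), Lgals3, which encodes galectin-3 (1.04, SE 0.31, adjusted p = 0.0495) and kept its call in 1 of the 12 fits that left out 1 library (without WT 2, for example, its log2 fold change was 0.92). Lyz2 was at 0.13 (SE 0.17). Their camera adjusted p was 0.00353 and the adjusted p = 0.506 with an estimated correlation, with 35 of 100 groupings as small, and 4 members were called without WT 1. The list's call was lost by fry (0.153) and with only KI 3 to 5 (0.673, median 0.07), while KI 1, 2 and 6 alone gave 7.07e-08 and a median of 0.48. In 7 more lists edgeR called 0 members, also adjusted over the list alone. Of these, endothelial markers (12 members, Fabp4 at 0.12, SE 0.09, and Cdh5 at 0.09, SE 0.09, camera adjusted p = 0.873), lymphocyte markers (7 members, Ptprc at 0.21, SE 0.19, and Cd4 at 0.11, SE 0.17, camera adjusted p = 0.947) and red blood cell markers (6 members, Hbb-bs at 0.02, SE 0.23, and Hba-a1 at 0.09, SE 0.22, camera adjusted p = 0.891) had 0 members at an unadjusted p under 0.05 and 0 in DESeq2 and voom. The red blood cell median of 0.04 differs in sign from the mean of -0.02 and the test. Smooth muscle and pericyte markers (12 members, Rgs5 at -0.14, SE 0.07, or 0.01 under scaling by library total, and Abcc9 at -0.15, SE 0.10, camera adjusted p = 0.947) had 1 member at an unadjusted p under 0.05 and 0 in DESeq2 and voom. Schwann cell markers (8 members, Cdh19 at 0.11, SE 0.15, camera adjusted p = 0.297, or 0.0172 without KI 2) and immediate early and heat shock genes (12 members, Egr1 at 0.56, SE 0.46, and Nr4a1 at 0.25, SE 0.28, camera adjusted p = 0.275) had 2 members each at an unadjusted p under 0.05 and 0 in DESeq2 and voom. Circadian clock genes (14 members, Tef at 0.27, SE 0.24, and Nr1d2 at 0.09, SE 0.23, camera adjusted p = 0.340) had 4 at an unadjusted p under 0.05, 2 in DESeq2 and 3 in voom. In the fits that left out 1 library edgeR called at most 1 Schwann cell marker (without KI 2), 1 immediate early or heat shock gene (without WT 6 or KI 1) and 2 higher and 2 lower clock genes (without WT 3). Under scaling by library total it called 7 macrophage markers, 3 smooth muscle and pericyte markers, 2 Schwann cell markers, 2 immediate early or heat shock genes and 1 clock gene, all higher.

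Of the 38 lists, 31 were tested and 16 were called by camera with the preset correlation, 10 higher and 6 lower, 13 of 19 functional lists and 3 of 12 lists of cell type markers and controls. With an estimated correlation camera called 0 lists (smallest adjusted p 0.121, with 9 lists at an unadjusted p under 0.05), and fry called 13. Other groupings of the same libraries called up to 20 lists, with a median of 11, and 15 of 100, the real one included, called as many as 16. With KI 1, 2 and 6 alone edgeR called few list members. Among them were 1 ion channel gene (10 with only KI 3 to 5), 1 fibroblast marker (4), 1 senescence gene (4) and 2 cell cycle genes (2). There it also called 1 gene of the stress and fetal program (6 higher and 1 lower with only KI 3 to 5), 1 p53 target (3 higher and 1 lower) and 1 stress response gene (3 higher and 1 lower). It called 0 interferon-stimulated genes and 0 respiratory chain genes there (13 and 9 at an unadjusted p under 0.05), against 6 and 4 with only KI 3 to 5. Neutrophil, adipocyte, mesothelial and epicardial, skeletal muscle, lung epithelium and thymocyte markers had too few members with counts to be tested: 3, 3, 2, 3, 0 and 1 of them passed the filter, with 0 lung epithelium genes above a count of 19 in any library.

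**Figure D4:**
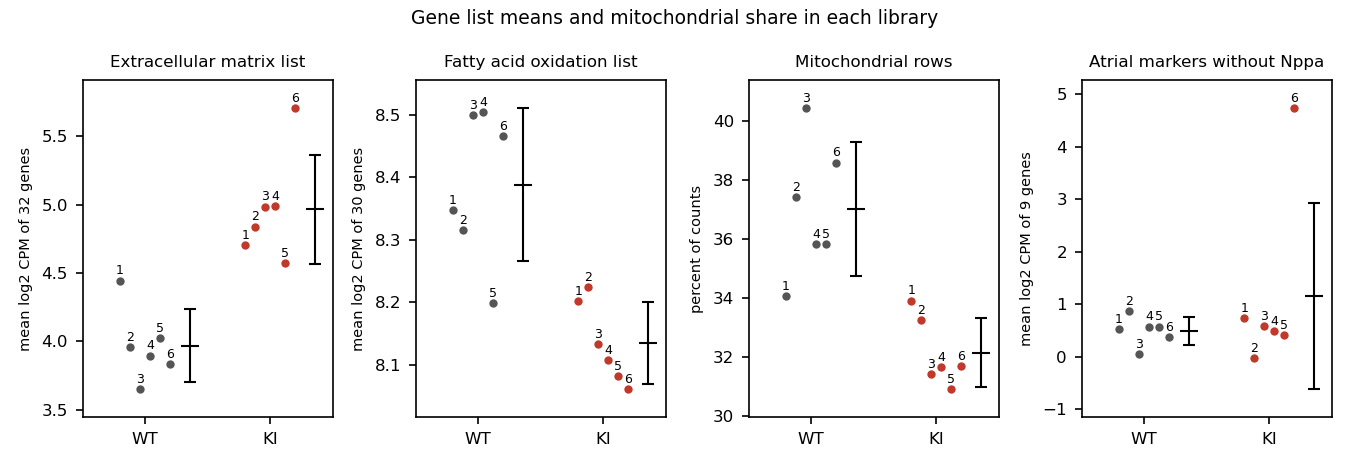
Mean log2 CPM per library of the extracellular matrix list, the fatty acid oxidation list and the 9 atrial markers other than Nppa, and the percent of counts on the mitochondrial chromosome (vertical axes), for WT and KI with mean and SD. The mitochondrial percent was 37.0 in WT and 32.1 in KI, and KI 6 stands apart in the atrial markers.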

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

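All tests of explanations in this part were chosen only after the results were seen. The genes singled out and reported and the library measures gave 204 groups of 6 values. In each group the gap between the highest or lowest library and the nearest other was divided by the range of the whole group. For genes this ratio was taken on log2 CPM, so it does not follow from the CPM printed beside it. In 10 of these groups the ratio was above Dixon's critical value for 6 values, where chance alone gives about 1 in 20, or 10.2 groups. In KI the ratio was 0.642 for Fmod (KI 6 at 21.7 CPM, median of the others 1.41), 0.754 for Lrtm1 (KI 3 at 55.1, others 162), 0.798 for Psrc1 (KI 2 at 1.32, others 0.857), 0.841 for Fancd2 (KI 2 at 2.57, others 1.42), 0.638 for Ccn2 (KI 1 at 141, others 290) and 0.719 for Dnajb9 (KI 2 at 26.2, others 23.0). In WT it was 0.650 for Nppa (WT 3 at 35.2, others 318), 0.632 for Tor1aip1 (WT 5 at 114, others 109), 0.738 for Trdn (WT 3 at 534, others 446) and 0.674 for Postn (WT 1 at 61.1, others 35.1). KI 2 held 3 of the 10 and WT 3 held 2. Their number is near what chance gives, so no explanation is offered for single ones.

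KI 6 held more RNA of several atrial genes than any other library: Myl7 was at 145 CPM against 0.426 in the next library, Sln at 52.4 against 0.200, Myl4 at 223 against 5.30 and Dkk3 at 64.4 against 12.9. A rise of this size shared by the KI animals is argued against by the 9 atrial markers other than Nppa. Their mean log2 CPM minus WT was -0.056 in the other 5 KI libraries (two-sided exact permutation p = 0.727, median 0.13, SD between markers 0.85). In KI 6 it was 4.25 (median 4.24). Dkk3, however, was higher without KI 6 too (adjusted p = 0.0151), and Nppa, left out here, was at 1.97 without KI 6 (adjusted p = 0.0628). The mean of -0.056 joins opposite moves, as 5 markers lay above 0 in KI 1 to 5 and 4 at or below it. Dkk3 was at 1.46, Stard10 at -1.04 and Sbk2 at -1.47. Without KI 6 edgeR called 1 atrial marker higher and 2 lower. Atrial tissue in this library may be the source, as 9 of 10 markers were highest in KI 6, but 5 of 10 stood at 4 times the next library or more, fewer than the 7 asked for. Bmp10, an atrial gene, was at 0.109 CPM in KI 6 against 0.135 in WT 6, and Nppa (1.14 times the next library) and Pam (1.28 times) are abundant in the other hearts too, so this stays open. A difference particular to this 1 animal was not tested.

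Fatty acid oxidation genes were lower in KI. The lower share of mitochondrial RNA, acting through the scaling, is argued against as the whole cause, since the list minus the median of all genes, which a scaling factor leaves as it is, was lower too (-0.28, two-sided exact permutation p = 0.00649, adjusted over 6 tests 0.0195), although scaling by library total moved the list median from -0.29 to -0.15 and the lower members from 20 to 11. The lower depth of KI 3 to 5 could have a part, but KI 1, 2 and 6, with 39.7 to 42.9 M counts, held most of the difference: -0.23 against -0.25 in all 6, in the mean log2 CPM of the list (two-sided exact permutation p = 0.0476, adjusted over 6 tests 0.0571). A smaller share of cardiomyocytes could too, but the ventricular markers moved by only -0.061 (two-sided exact permutation p = 0.294), and the list minus these markers was -0.19 in KI minus WT (two-sided exact permutation p = 0.0433, adjusted 0.0571). Neither of the last 2 tests passes after adjustment, so depth and cell share are not excluded beside the genotype, although these values go against each of the 2 as the whole cause.

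Extracellular matrix genes were higher in KI. A larger share of fibroblasts is argued against as the whole cause, since the list rose by 0.57 (log2) more than 11 fibroblast markers it does not hold (two-sided exact permutation p = 0.00649, adjusted over 6 tests 0.0195). Atrial tissue in KI 6 is argued against as the cause by the 21 members called higher without that library. A change in KI 3 to 5 alone is argued against by KI 1, 2 and 6, which lay 1.12 above WT (two-sided exact permutation p = 0.0119, the smallest that 3 against 6 allows, adjusted 0.0238). The genotype, a fibroblast state that differs, and the series of second title numbers, which runs with the genotype, may each contribute and remain open. Litter and cohort are not named in the labels and remain open too.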

How the results depend on the processing

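Leaving out the mitochondrial genes was chosen after the data were seen, and the other alternatives were planned. None of the 105 genes singled out and none of the 31 lists changed direction with a call under any alternative run. Of the 1365 genes called, at least 99.9% kept their direction in each one, counted over the 1251 with a value under the filter of CPM above 1 and the 1350 without the mitochondrial genes. Of the 83 singled-out genes past the threshold, 64 stayed past it in every fit that left out 1 library, 76 without KI 6, 71 with only KI 3 to 5, 16 without KI 3 to 5 and 11 in every planned fit tested. Under scaling by library total 2957 genes were higher and 191 lower, with Lemd2 at -0.21, which follows from the shift of the median of all genes. DESeq2 called 1067 lower genes and voom 1265, and the cause was not tested. A test against a fold of 1.2 called 78 higher and 25 lower genes and not Lemd2 at -0.36, as it asks for a larger change. The replicate number as a block gave 220 higher, 212 lower and Lemd2 at -0.37 (adjusted p = 0.0889), of which 214 and 204 were genes called without the block. In the labels WT and KI animals share these numbers, but 0 of 6 such pairs had a correlation over 0.1, and the block uses up degrees of freedom. Without KI 3 to 5 the counts were 68 and 22, of which 59 and 19 were called with all libraries, and with only KI 3 to 5 there were 802 higher and 1195 lower genes, with Lemd2 at -0.23. Both set 3 KI libraries against 6 of WT, and KI 3 to 5 also lie apart from KI 1, 2 and 6 in the structure described under other observations. The cause of neither count was tested. A correlation estimated from the data left 0 lists called by camera and fry called 13. Leave-one-out gave 390 to 714 higher genes, 338 to 833 lower genes, 15 to 18 lists and Lemd2 from -0.41 to -0.31. DESeq2 and the test against a fold of 1.2 give no list value, DESeq2 gave no adjusted p for 33 genes, Fmod among them, and the covariate for sex was not run because all libraries come from males. With 6 libraries per group, simulated changes of 1.5-fold were called in 54.0% of genes. The simulation changed 220 of 15452 genes, while 1365 of 15602 were called in the data. As the adjusted threshold depends on the share of genes that differ, 54.0% is not the power here, but smaller differences may be missed.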

Other observations

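The counts of other groupings of the libraries were planned, and the genes given after them were chosen only after their values were seen. Of 100 groupings of the 12 libraries into 6 and 6, only 1, the real one, gave as many as its 1365 genes, and the highest other gave 844. The 99 others were drawn at random, so a number this high was seen in no more than 1 of 100 groupings. This does not tell the genotype from the series of second title numbers, which runs with it. For the number of lists chance is not excluded: 15 of the 100 groupings called as many as the real 16, and the highest other called 20. The grouping with 20 lists put 4 of the 6 KI libraries on 1 side, and such groupings can carry part of the difference between KI and WT. Yet groupings with 3 KI libraries on each side called up to 16 lists. The other groupings called a median of 11 lists, and over all 100 the matrix list was called in 65 and the cell cycle list in 68. The preset correlation of camera thus calls lists too readily in these libraries, so its small adjusted p values are no firm evidence by themselves.

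The grouping with 844 genes set WT 1, 4 and 6 with KI 3, 4 and 5 against the others, and the next highest gave 2 genes, which points to a structure of the samples apart from the genotype. Neat1 was between 543 and 888 CPM in these 6 libraries and between 223 and 387 in the others. Leng8 was between 87.4 and 129 against 45.6 and 65.2. Both groups hold 3 libraries of each kind, and the planned fit with 1 surrogate variable gave 880 higher and 848 lower genes between KI and WT, of which 682 and 673 were called without it. As KI 3 to 5 lie on 1 side of this structure and KI 1, 2 and 6 on the other, fits with either set of KI libraries alone carry it too.

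Several genes outside the lists stood apart in every KI library. Rpl3 was higher by 0.46 (log2, SE 0.06, adjusted p = 0.00231) and its muscle paralog Rpl3l lower (-0.70, SE 0.11, adjusted p = 0.00355), each with 6 of 6 KI libraries beyond all WT libraries. Eef1a1 was higher by 0.42 (SE 0.07, adjusted p = 0.00531), while Eef1a2 was at -0.07 (SE 0.06, adjusted p = 0.503). Reads shared between such paralogs were split between them by the counting. Myh8 was higher by 2.06 (SE 0.26, adjusted p = 0.00159) and Scn10a lower (-0.77, SE 0.11, adjusted p = 0.00272). Apod was higher by 1.27 (SE 0.14, adjusted p = 0.000693).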
